A study of Mus musculus with 26 samples.

How the data were processed

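RNA was sequenced from resident alveolar macrophages (AM) and bone marrow-derived macrophages (BM) sorted from mouse lungs without lipopolysaccharide (day 0, AM alone) or 1, 3 and 7 days after it was given into the trachea. The deposited values are raw counts per Ensembl gene, 1 column per library, and the authors name FastQC 0.11.9, Trimmomatic 0.39, HISAT2 2.1.0, featureCounts 2.0.0 and genome build GRCm38 for making them. Their notes give no settings, no annotation release and no strand setting for the counting. The labels describe stranded libraries of poly(A)-selected RNA. They state neither the sorting gates nor the sex of the mice.

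The table holds 55487 genes and 26 libraries, and no column lacks a listed sample. GENCODE M21 gave a symbol and a position for 55227 IDs, while 260 IDs, with 0.565% of the counts, have no symbol and keep their ID. A symbol that 116 genes share with another gene is written with the ID. The 37 mitochondrial genes have 0 counts in all libraries, so no mitochondrial share could be computed.

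The libraries form 7 groups of 3 to 5 by cell type and day. They were fitted together in edgeR 4.0.16 (R 4.3.3) with 1 coefficient per group, TMM scaling, the filter filterByExpr (minimum count 10) and the robust quasi-likelihood F test. The filter left 17143 genes, which hold 99.9% of the counts. P-values were adjusted by Benjamini-Hochberg over these genes in each of 11 comparisons, and a gene is called at an adjusted p under 0.05. The comparisons are BM against AM at days 1, 3 and 7, each AM day against day 0, successive days within each cell type, and the interaction of cell type with day 7 against day 3. Where all libraries of a group have 0 counts, no fitted fold is given but a lower bound, computed from a floor of 3 counts over the group. The depth of each library sets the precision, and these bounds cover counting error alone.

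Lists of genes were fixed before the data were examined, as were the comparisons, the tests and most alternatives to the processing. The 25 lists are alveolar macrophage identity, blood monocyte, monocyte-derived and tissue macrophage, inflammatory cytokines and chemokines, interferon-stimulated genes, TLR and NF-kB signalling, MHC class II presentation, lysosome, efferocytosis, mitochondrial fatty acid oxidation, peroxisome, cholesterol synthesis, oxidative phosphorylation, glycolysis, cell cycle, repair and matrix, dissociation and stress response, and markers of neutrophils, lung epithelium, T and NK cells, B cells, dendritic cells, endothelium and fibroblasts, eosinophils and erythroid cells. Lysosome, efferocytosis, mitochondrial fatty acid oxidation and peroxisome are themes of the study itself, so their results are not independent of it. Lists with at least 3 tested members, 23 in all, were tested with camera in limma 3.58.1 on voom values with weights of at most 1000, a preset correlation of 0.01 and adjustment over the 23 lists. Camera was repeated with a correlation estimated from the data. For the counts of called members, p-values were also adjusted over the list alone.

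The genes named follow a rule written down with the lists. In each list they are up to 4 called members with the largest change, a mean of at least 5 CPM in the higher group and no overlap between the groups, and the most abundant member. Added to these are the 5 largest rises and the 5 largest falls among called genes under the same conditions, without gene models, pseudogenes and receptor segments, and always Siglecf, Itgax, Itgam, Ly6c2, Ccr2, Pparg, Il1b, Tnf and Mki67. For the interaction overlap was allowed. Some genes that the rule names are not reported. Each library's count of genes detected, its correlation with its group and its Xist and Y-linked RNA were recorded. Principal components were computed on log2(CPM + 1).

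The alternatives fixed beforehand were DESeq2 size factors in edgeR, library size alone, DESeq2 1.42.0 with its Wald test, no filter on low counts, a stricter filter (5 CPM in 3 libraries), a fit to the compared groups alone, the replicate number of the titles or of the descriptions as a block, the library number range within 1 prefix as a term, and leaving out each of the 26 libraries in turn. Alternatives added after seeing the data were leaving out BM_day1.3 and BM_day3.1, which have the fewest genes detected, leaving out all BM day 1 libraries, and the level of 4 Y-linked genes as a covariate. The replicate numbers do not pair the samples: after removing group means, libraries with the same number had correlations between −0.047 and 0.069. The procedure was tested on simulated data with known folds in 4 comparisons. It called 2.99% to 11.9% of genes changed 2-fold, 29.9% to 41.8% at 4-fold and 54.5% to 60.6% at 8-fold. Unchanged genes made up 1.41% to 4.29% of its calls. These shares hold for those data alone, not for the real groups, whose spread differs.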

Results

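RNA was sequenced from macrophages sorted from mouse lungs that had received no lipopolysaccharide (LPS, day 0) or were taken 1, 3 or 7 days after LPS was placed in the trachea. LPS is a component of the wall of Gram-negative bacteria, and in the airway it causes acute inflammation. The labels name resident alveolar macrophages (AM), the cells that patrol the air spaces of an uninflamed lung, and macrophages derived from bone marrow (BM), which enter the lung during inflammation. The 26 libraries formed 7 groups: AM day 0 (n = 3), AM day 1 (n = 4), AM day 3 (n = 3), AM day 7 (n = 4), BM day 1 (n = 5), BM day 3 (n = 4) and BM day 7 (n = 3). Libraries are named here by group and replicate, as in AM_day0.1. The labels do not say that replicates are separate animals, so the p-values measure the spread between these samples, which may be technical in part.

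The values are read counts per gene. Total counts per library ran from 9176202 to 80816742, with 35.8 to 80.8 M in AM day 0, 9.18 to 15.1 in AM day 1, 11.2 to 14.5 in AM day 3, 9.95 to 27.5 in AM day 7, 13.02 to 20.01 in BM day 1, 11.4 to 22.3 in BM day 3 and 10.1 to 24.7 in BM day 7. Replicates were alike at day 0 and day 7, with a median Pearson correlation of log2 CPM (counts scaled to a common library total) between 0.979 and 0.985 in those groups. They spread more at days 1 and 3, with a median of 0.913 in BM day 1 and 0.886 in BM day 3. BM_day3.1 stood apart, with a median correlation of 0.734 with its group and 9126 genes detected against 11380 to 12968 in the rest of its group. Its most abundant transcript was Col1a1, a collagen chain made by fibroblasts. BM_day1.3 had 9684 genes detected and a median correlation of 0.830 with its group. Components 1 and 2 of a principal component analysis held 27.7% and 18.1% of the variance.

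**Figure D1:**
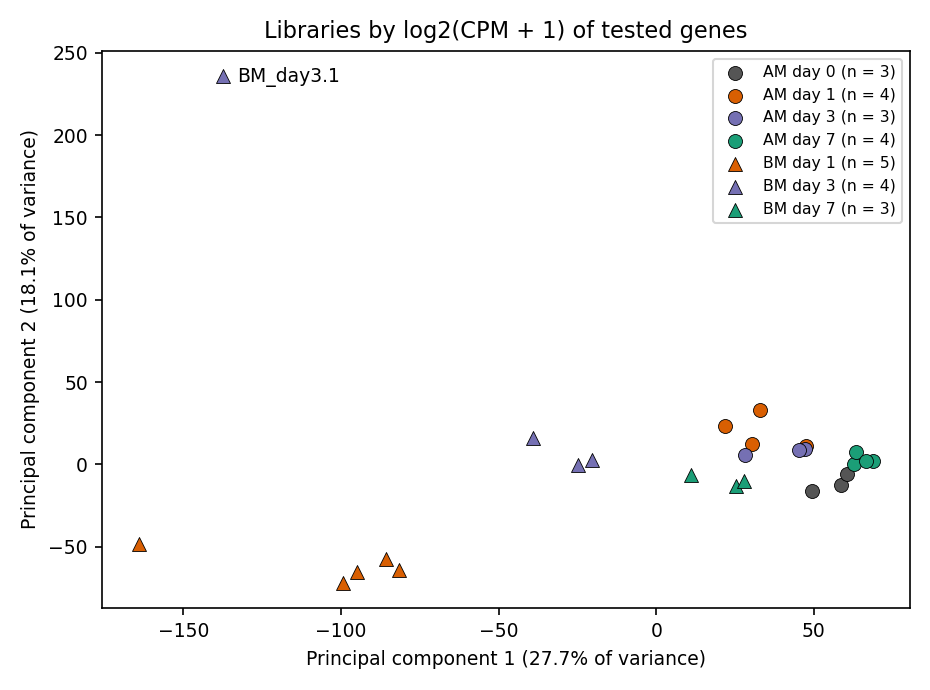
Position of each of the 26 libraries on principal components 1 and 2 of log2(CPM + 1) over 17143 tested genes; each point is 1 library, with colour for the day and shape for the cell type. Component 1 holds 27.7% and component 2 holds 18.1% of the variance, and BM_day3.1, marked by name, lies away from the other BM day 3 libraries.

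The groups differed in the sex of the mice as read from RNA. Transcripts of 4 Y-linked genes summed to between 146 and 227 CPM in every AM day 0, day 1 and day 3 library and to at most 4.09 CPM in every AM day 7 and BM day 7 library, where Xist, a transcript of the inactive X chromosome, was abundant. In BM day 1 the sum was 7.75 to 38.4 CPM with Xist at 472 to 910 CPM. In BM day 3 it was 0.165 and 0.0479 in replicates 1 and 2, and 167 and 169 in replicates 3 and 4. AM_day0.1 carried both, with 144 CPM of Xist beside 146 CPM of Y-linked RNA. AM day 7 against any earlier day and BM against AM at day 1 thus also compare sexes. So, in part, do BM against AM at day 3, BM between successive days and the interaction. The AM day 0 and the BM day 1 libraries each carry a library-name prefix that no other group has, so a comparison with either group is also one between prefixes.

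At day 1 transcripts that mark the resident cells were low in the BM-derived cells, and those of blood monocytes were high (BM day 1, n = 5, against AM day 1, n = 4). Effects are log2 fold changes ± SE from edgeR. Car4, a carbonic anhydrase of alveolar macrophages (ENSMUSG00000000805, chromosome 11, 84957786 to 84966044 of GRCm38), differed by −6.78 ± 0.70, Atp6v0d2, a proton pump subunit, by −6.19 ± 0.35, and the chitinase-like secreted protein Chil3 by −4.55 ± 0.38 (largest adjusted p = 2.2e-07). Siglecf, the lectin used to recognise resident alveolar macrophages (ENSMUSG00000039013, chromosome 7, 43351341 to 43359531), was lower by the same test (−3.07 ± 0.52, adjusted p = 0.00011), as was Pparg, the nuclear receptor that sets the alveolar macrophage programme (−1.59 ± 0.30). Members of the alveolar macrophage identity list were lower (1 of 20 higher and 18 lower, adjusted over the list alone 1 and 18, camera adjusted p = 2.4e-07, or 0.17 with an estimated correlation). In the other direction stood Ccr2, the receptor by which monocytes leave the bone marrow (3.34 ± 0.57), Ace (5.47 ± 0.55), Spn (4.16 ± 0.50) and Plac8 (4.02 ± 0.57), with a largest adjusted p of 0.00011. Members of the blood monocyte list were higher (13 of 17 higher and 1 lower, adjusted over the list alone 14 and 2, camera adjusted p = 2.9e-05, or 0.055 with an estimated correlation). The chemokine receptor Cx3cr1 (3.84 ± 0.77) was higher too, while Gpnmb, a glycoprotein of lipid-laden macrophages, was lower (−3.22 ± 0.36), and the monocyte-derived and tissue macrophage list did not pass its test (9 of 20 higher and 4 lower, adjusted over the list alone 10 and 4, camera adjusted p = 0.28).

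Genes of lysosomes and of oxidative metabolism were lower in the BM-derived cells at day 1. The cathepsins Ctsk (−5.42 ± 0.60) and Ctsd (−2.40 ± 0.21) and the lysosomal membrane proteins Cd63 (−3.42 ± 0.29) and Cd68 (−2.30 ± 0.25) had a largest adjusted p of 5.9e-07. Lysosome genes as a list were lower (1 of 30 higher and 22 lower, adjusted over the list alone 1 and 24, camera adjusted p = 3.3e-08, or 0.17 with an estimated correlation, not independent of the study's themes), as were those of oxidative phosphorylation (19 of 27 lower, adjusted over the list alone 19, camera adjusted p = 8.3e-10, or 0.072 with an estimated correlation), with Cox5b at −2.27 ± 0.30 and Atp5c1 at −2.28 ± 0.34. Mitochondrial fatty acid oxidation followed (12 of 19 lower, adjusted over the list alone 13, camera adjusted p = 9.4e-06, or 0.0093 with an estimated correlation, not independent of the study's themes), with Eci2 at −2.19 ± 0.33. Peroxisome genes were lower (9 of 30 lower, adjusted over the list alone 10, camera adjusted p = 0.00030, or 0.21 with an estimated correlation, not independent of the study's themes): Pex11a, which acts in the division of peroxisomes, was at −6.07 ± 0.91, and Pecr, an enoyl-CoA reductase, had 0 counts in every BM day 1 library and was at least 197-fold lower.

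TLR and NF-kB signalling genes were higher in the BM-derived cells at day 1 (12 of 19 higher, adjusted over the list alone 12 higher and 2 lower, camera adjusted p = 0.00023, or 0.24 with an estimated correlation), among them Nfkbiz (2.44 ± 0.26) and Rel (2.40 ± 0.29). The inflammatory cytokine and chemokine list was mixed (2 of 24 higher and 9 lower, adjusted over the list alone 2 and 10, camera adjusted p = 0.063). Il1b was higher in BM (1.04 ± 0.22), whereas the neutrophil attractant Cxcl3 (−4.48 ± 0.49) and Ccl9 (−3.82 ± 0.37) were higher in AM (largest adjusted p = 0.00091). Vegfa, the endothelial growth factor (4.57 ± 0.88), and Thbs1, the matrix protein thrombospondin (4.97 ± 0.97), were higher. Transcripts that lack a poly(A) tail also stood high in these libraries: replication histone genes summed to 681 to 1957 CPM in BM day 1 and to 46.0 to 327 CPM in all other libraries, and Hist1h4d was at least 1023-fold higher than in AM day 1, where it had 0 counts. ENSMUSG00000118642, a gene without a symbol in the annotation and singled out after its values were seen, was the most abundant transcript of all 5 BM day 1 libraries and of no other (7.18 ± 0.80, adjusted p = 6.6e-07). Neutrophil markers were higher by camera (3 of 14 higher and 1 lower, adjusted over the list alone 3 and 1, camera adjusted p = 0.0057, or 0.40 with an estimated correlation), with the receptor Csf3r at 2.28 ± 0.32 and Lcn2 at −2.09 ± 0.56.

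The test called 4969 of 17143 genes, 2600 higher and 2369 lower in BM-derived cells. Each called gene named with a value here and in the comparisons that follow had every library of 1 group above every library of the other, unless an overlap is stated and except for the interaction. Chance gives such a separation to 10% of genes for 3 libraries against 3, 5.71% for 3 against 4 and 1.59% for 4 against 5. The count was 2313 with the Y-linked level as a covariate. Of the 31 genes named here as called, 25 stayed called under every alternative run. 6 of them were lost with the Y-linked level as a covariate. At least 1 alternative ended the call of these lists named here: neutrophil markers (adjusted p = 0.90 with the Y-linked level as a covariate; range 0.00031 to 0.90).

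At day 3 the resident programme was still low in the BM-derived cells, which now also carried transcripts of tissue macrophages (BM day 3, n = 4, against AM day 3, n = 3). Krt79 (−4.92 ± 0.88) and Krt19 (−5.24 ± 1.03), keratins that mark alveolar macrophages, Siglecf (−3.70 ± 0.60), Pparg (−2.51 ± 0.35) and Chil3 (−2.85 ± 0.40) were lower, with a largest adjusted p of 0.0066. The alveolar macrophage identity list was lower (17 of 20 lower, adjusted over the list alone 18, camera adjusted p = 3.2e-12, or 0.073 with an estimated correlation). The complement genes C1qa (ENSMUSG00000036887, chromosome 4, 136895917 to 136898803) at 2.57 ± 0.49, C1qb at 2.38 ± 0.51 and C1qc at 2.35 ± 0.59, and the lipid carrier Apoe at 2.03 ± 0.55, were higher in BM (largest adjusted p = 0.041), and so was the monocyte-derived and tissue macrophage list (7 of 20 higher and 1 lower, adjusted over the list alone 8 and 1, camera adjusted p = 6.7e-12, or 0.026 with an estimated correlation). Ccr2 (2.97 ± 0.64) and Ace (3.26 ± 0.56) led the blood monocyte list (4 of 17 higher, adjusted over the list alone 6, camera adjusted p = 8.5e-08, or 0.016 with an estimated correlation), while Ly6c2, the surface protein of inflammatory monocytes, was abundant in both cell types and did not pass the test (0.66 ± 0.51, adjusted p = 0.55).

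Some chemokines and lipid enzymes were lower in the BM-derived cells at day 3. The neutrophil attractant Cxcl1 (−3.86 ± 0.66), the cytokine Il18 (−4.21 ± 0.99) and Cxcl3 (−2.07 ± 0.51) passed the test (largest adjusted p = 0.025), but the cytokine list as a whole did not (5 of 24 lower, adjusted over the list alone 6, camera adjusted p = 0.42). Hmgcs1, an early enzyme of sterol synthesis (−1.87 ± 0.26), and Insig1, a sensor of sterol supply (−1.27 ± 0.31), were lower, and so was the cholesterol synthesis list (3 of 22 lower, adjusted over the list alone 8, camera adjusted p = 0.0013, or 0.40 with an estimated correlation). Acaa1b, a peroxisomal thiolase, was at −5.30 ± 1.13. Sparc (7.02 ± 1.81) and Col4a1 (4.73 ± 1.03), genes of the extracellular matrix, were higher, in a group whose replicate 1 had Col1a1 as its most abundant transcript. The endothelium and fibroblast list was higher by camera (0 of 11 passed edgeR's test, 5 had an unadjusted p under 0.05 and 3 passed DESeq2's, adjusted over the list alone 3, camera adjusted p = 0.0013, or 0.074 with an estimated correlation). Neutrophil markers were higher by camera (1 of 14 higher and 1 lower, adjusted over the list alone 4 and 1, camera adjusted p = 0.0077, or 0.40 with an estimated correlation), with Csf3r at 1.47 ± 0.35. Their mean was highest in BM_day3.1 (5.59 log2 CPM, against 0.23 to 2.78 in the rest of its group). Without BM_day3.1 the mean log2 fold change of this list went from 2.44 to −0.40.

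The test called 683 genes, 171 higher and 512 lower in BM-derived cells. The count was 398 without a filter on low counts, 1987 with DESeq2, 6 in a fit to the compared groups alone, 1059 without BM_day1.3 and BM_day3.1, 1130 without the BM day 1 libraries and 188 with the Y-linked level as a covariate. It was 225 without AM_day3.3, 250 without AM_day3.1 and 400 without BM_day3.3. Of the 20 genes named here as called, 1 stayed called under every alternative run. 19 of them were lost in a fit to the compared groups alone and 11 with the Y-linked level as a covariate. A fit without 1 of AM_day3.3, AM_day3.1 and BM_day3.3 ended 4 to 10 of these calls, and no other single library ended more than 2. Among the lists named here, a call ended under at least 1 alternative for cholesterol synthesis (adjusted p = 0.055 without BM_day3.2; range 4.0e-05 to 0.055), endothelium and fibroblast markers (adjusted p = 0.057 with the Y-linked level as a covariate; range 0.00013 to 0.057) and neutrophil markers (adjusted p = 0.83 with the Y-linked level as a covariate, 0.41 without BM_day3.1 and 0.38 without BM_day1.3 and BM_day3.1; range 1.2e-05 to 0.83).

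At day 7 the genes that separated the cells were mostly higher in the BM-derived cells (BM day 7, n = 3, against AM day 7, n = 4). C1qa (4.95 ± 0.50), C1qb (4.97 ± 0.53), C1qc (4.89 ± 0.61) and Apoe (4.81 ± 0.57) were higher, with a largest adjusted p of 2.3e-05. The monocyte-derived and tissue macrophage list was higher (10 of 20 higher, adjusted over the list alone 13 higher and 1 lower, camera adjusted p = 1.5e-18, or 0.0018 with an estimated correlation). Monocyte genes were higher as well (9 of 17 higher, adjusted over the list alone 12, camera adjusted p = 3.4e-09, or 0.0018 with an estimated correlation): Ly6c2 (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970) was at 5.39 ± 0.61, the integrin chain Itgam (CD11b) at 4.65 ± 0.43, the transglutaminase F13a1 at 5.50 ± 0.80 and Plac8 at 4.66 ± 0.65 (largest adjusted p = 0.00019). Reads of Ly6c2 may be split with the near-identical gene Ly6i, so their separate values are uncertain.

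Part of the resident programme no longer passed the test at day 7. Lpl, which frees fatty acids from lipoproteins (−1.83 ± 0.31), the cholesterol exporter Abcg1 (−1.28 ± 0.24) and Ear2 (−1.91 ± 0.47, a ribonuclease whose reads may be split with Ear1) were lower (largest adjusted p = 0.034). Siglecf (−2.04 ± 0.60, adjusted p = 0.11), Chil3 (−1.47 ± 0.40, adjusted p = 0.074) and Pparg (−1.11 ± 0.35, adjusted p = 0.14) were not called, yet the alveolar macrophage identity list was lower (3 of 20 lower, adjusted over the list alone 8, camera adjusted p = 1.5e-28, or 0.0018 with an estimated correlation). BM_day7.1 and BM_day7.2 carried resident genes at a median of 36.4% and 37.6% of the AM day 7 level and BM_day7.3 at 5.47%, over 79 genes chosen after their values were seen.

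Antigen-presenting and some inflammatory genes were higher in BM-derived cells at day 7, the MHC class II list mainly in BM_day7.1 and BM_day7.2. The cytokine and chemokine list was higher by camera (3 of 24 higher, adjusted over the list alone 6, camera adjusted p = 0.013, or 0.37 with an estimated correlation). Saa3, an acute phase protein (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), differed by 6.17 ± 0.91 and Ptgs2, the inducible cyclooxygenase, by 3.33 ± 0.55 (largest adjusted p = 0.00079). Socs3, a brake on cytokine signalling (2.52 ± 0.25), Traf1 (2.06 ± 0.35) and Nfkbiz (1.64 ± 0.28) led the TLR and NF-kB list (4 of 19 higher, adjusted over the list alone 4, camera adjusted p = 0.00029, or 0.19 with an estimated correlation). The MHC class II list was higher (3 of 13 higher, adjusted over the list alone 7, camera adjusted p = 0.00018, or 0.24 with an estimated correlation), with H2-Eb1 at 2.65 ± 0.68 and its transactivator Ciita at 2.33 ± 0.56. Lysosome genes were higher (3 of 30 higher, adjusted over the list alone 10 higher and 1 lower, camera adjusted p = 0.00080, or 0.35 with an estimated correlation, not independent of the study's themes), with the protease Lgmn at 1.49 ± 0.23 and Ctsb at 1.17 ± 0.21. Mitochondrial fatty acid oxidation was lower by camera (1 of 19 lower, adjusted over the list alone 1, camera adjusted p = 1.1e-08, or 0.00091 with an estimated correlation, not independent of the study's themes), with the Hadha subunit at −0.89 ± 0.21. B cell markers were higher (1 of 8 higher, adjusted over the list alone 2, camera adjusted p = 3.1e-05, or 0.026 with an estimated correlation). Ighm led them (4.59 ± 1.03, adjusted p = 0.015). The mean of the B cell list was 3.28 and 3.14 log2 CPM in BM_day7.1 and BM_day7.2, but −0.68 in BM_day7.3 (AM day 7, −1.62 to −0.78). Whether other cells in BM_day7.1 and BM_day7.2 carried the MHC class II transcripts was not tested.

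The test called 303 genes, 254 higher and 49 lower in BM-derived cells. The count was 615 with DESeq2, 612 without BM_day1.3 and BM_day3.1, 200 without BM_day7.3 and 463 without BM_day3.1. A fit to the compared groups alone called 2948, 1616 higher and 1332 lower. It also turned the order of the 2 days, with 6 genes at day 3 (main fit 683). Of the 22 genes named here as called, 15 stayed called under every alternative run. 6 of them were lost with the library number range as a term and 4 with the title number as a block. Between 3 and 5 of these calls ended without 1 of AM_day7.2, AM_day7.3, AM_day7.4, BM_day7.1, BM_day7.2 and AM_day7.1, and no other single library ended more than 2. At least 1 alternative ended the call of these lists named here: inflammatory cytokines and chemokines (adjusted p = 0.074 without a filter on low counts and 0.073 without BM_day7.2; range 0.00012 to 0.074) and lysosome (adjusted p = 0.098 without BM_day7.3; range 1.1e-06 to 0.098).

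Some genes separated the cell types at both day 3 and day 7. Of the 683 and 303 genes called, 75 were higher in BM at both times, where 2.53 are expected by chance, 33 were lower at both (1.46 by chance) and 1 changed sides. Across all tested genes, which are not independent replicates, the log2 fold changes at the 2 days had a Pearson r of 0.156 and a Spearman rho of 0.273. Apart from leaving out 1 library, alternatives gave 1 (in a fit to the compared groups alone) to 187 (with DESeq2) genes higher at both days. It was 12 without AM_day3.3, 13 without AM_day3.1 and 47 without BM_day3.3. Apart from leaving out 1 library, alternatives gave 2 (in a fit to the compared groups alone) to 82 (without BM_day1.3 and BM_day3.1) genes lower at both days. It was 10 without BM_day7.3, the lowest, and 56 without BM_day3.1, the highest.

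**Figure D2:**
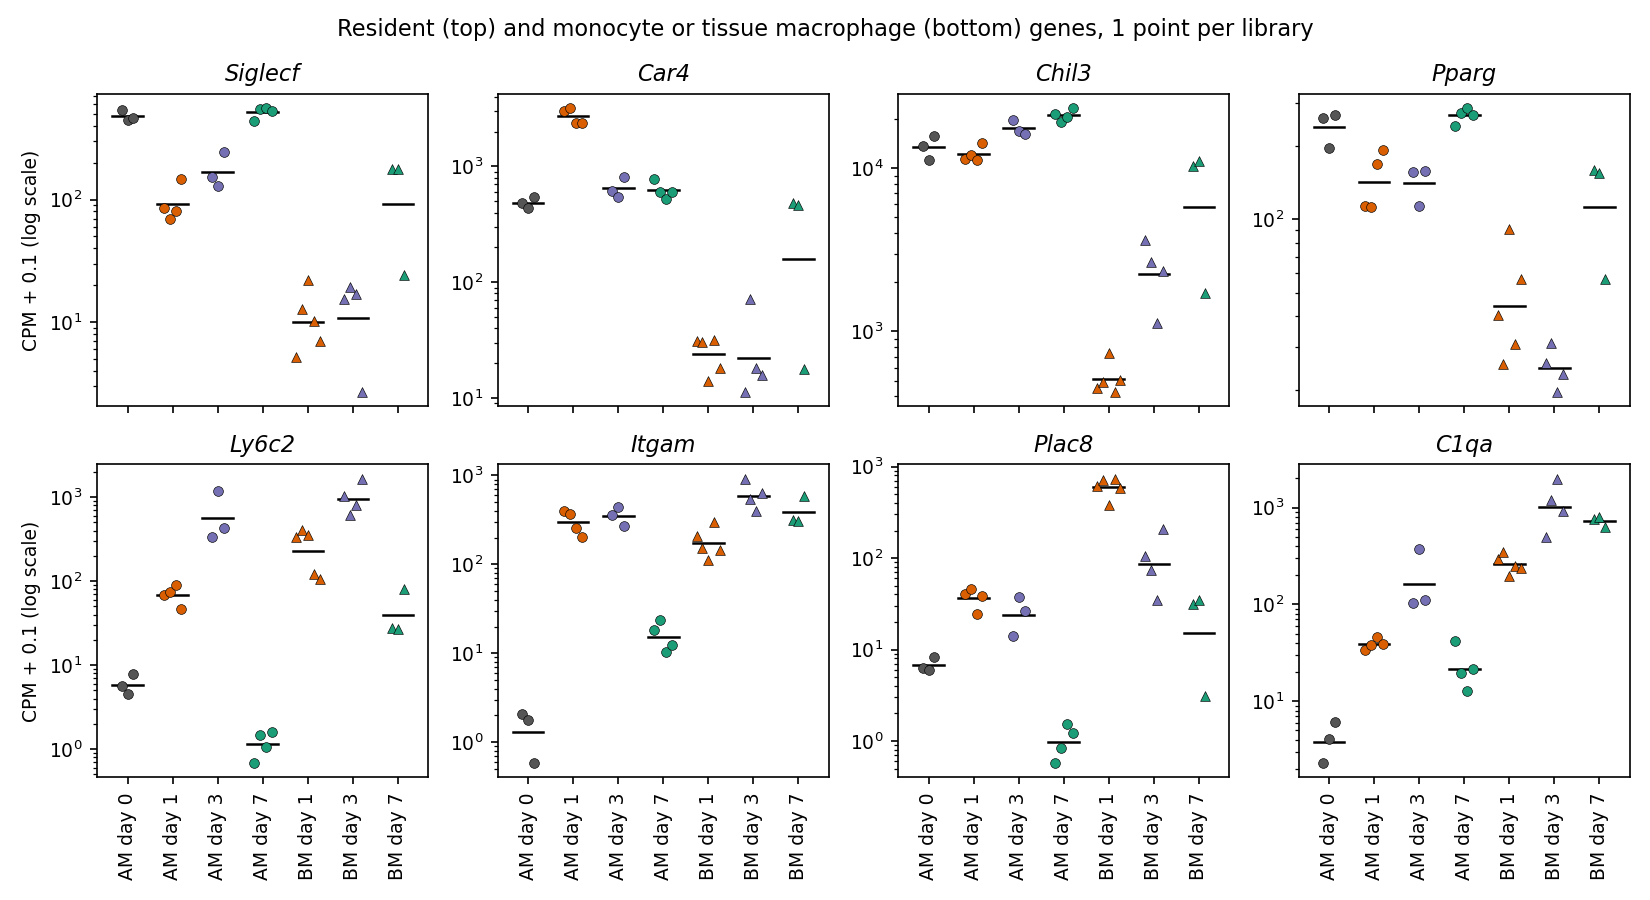
CPM of 4 resident genes (Siglecf, Car4, Chil3, Pparg) and 4 genes of monocytes and tissue macrophages (Ly6c2, Itgam, Plac8, C1qa) on a log axis after adding 0.1 CPM, 1 point per library and a bar at the group mean of the log values. Plac8 stands higher in every BM day 1 and BM day 7 library than in each AM library of the same day.

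Resident macrophages 1 day after LPS carried an interferon and chemokine response (AM day 1, n = 4, against AM day 0, n = 3). Rsad2 (viperin) rose by 6.41 ± 0.77, Oasl2 by 6.14 ± 0.48 and the T cell attractant Cxcl9 by 7.33 ± 0.85 (largest adjusted p = 4.3e-06). The interferon-stimulated list rose (19 of 24 rose, adjusted over the list alone 21, camera adjusted p = 1.1e-18, or 0.043 with an estimated correlation). Nos2, the inducible nitric oxide synthase (9.66 ± 1.29), Saa3 (7.47 ± 1.08), Cxcl3 (5.91 ± 0.66), Ccl9 (4.33 ± 0.47) and Il1b (1.64 ± 0.26) rose (largest adjusted p = 0.00011), as did the cytokine and chemokine list (10 of 24 rose, adjusted over the list alone 16 rose and 2 fell, camera adjusted p = 2.1e-11, or 0.039 with an estimated correlation). Tnf did not pass the test (−1.06 ± 0.37, adjusted p = 0.094). Lcn2, an iron-binding protein also made by neutrophils, rose by 10.65 ± 1.02 with S100a9 (7.30 ± 1.67) in a list of neutrophil markers (4 of 14 rose, adjusted over the list alone 5, camera adjusted p = 0.0020, or 0.28 with an estimated correlation).

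The monocyte-derived and tissue macrophage list rose in the resident cells at day 1 (9 of 20 rose and 1 fell, adjusted over the list alone 9 and 1, camera adjusted p = 0.0020, or 0.27 with an estimated correlation). The blood monocyte list did not pass its test (7 of 17 rose and 3 fell, adjusted over the list alone 8 and 4, camera adjusted p = 0.078). Itgam rose by 7.77 ± 0.56, Hp (haptoglobin) by 7.52 ± 0.45, Mmp14 by 6.65 ± 0.47 and C1qb by 3.63 ± 0.55 (largest adjusted p = 0.00013). Siglecf (−2.34 ± 0.57) and Krt19 (−3.60 ± 0.96) fell. Glycolysis genes rose (9 of 18 rose, adjusted over the list alone 11, camera adjusted p = 3.6e-13, or 0.042 with an estimated correlation), with the glucose transporter Slc2a1 at 2.82 ± 0.31, and oxidative phosphorylation rose as well (2 of 27 rose, adjusted over the list alone 9, camera adjusted p = 2.2e-11, or 0.039 with an estimated correlation). Efferocytosis genes, which serve the uptake of dead cells, fell (6 of 22 fell, adjusted over the list alone 1 rose and 10 fell, camera adjusted p = 0.00030, or 0.039 with an estimated correlation, not independent of the study's themes): Rxra was at −1.36 ± 0.22, the cholesterol exporter Abca1 at −1.14 ± 0.31, and Timd4, a receptor for phosphatidylserine on dying cells, had 0 counts at day 1 and was at least 166-fold lower. Cell cycle genes fell (2 of 26 fell, adjusted over the list alone 9, camera adjusted p = 0.00018, or 0.27 with an estimated correlation), with Top2a at −2.66 ± 0.54. T and NK cell markers fell (2 of 14 fell, adjusted over the list alone 2, camera adjusted p = 0.00016, or 0.039 with an estimated correlation), Cd8a by at least 150.4-fold and Cd3d by at least 108-fold, both with 0 counts at day 1. Most members of the dissociation and stress response list, which sample handling can induce, fell when adjusted over the list alone, though it did not pass camera (1 of 12 rose and 6 fell, adjusted over the list alone 1 and 9, camera adjusted p = 0.18), with Fosb at −2.06 ± 0.38 and Ier2 at −1.45 ± 0.28.

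The test called 1077 genes, 552 up and 525 down, around a median over all genes of −0.20. The count was 2168 with DESeq2, 1862 in a fit to the compared groups alone and 2425 without BM_day1.3 and BM_day3.1. It was 558 without AM_day0.1, 606 without AM_day0.2 and 1732 without BM_day3.1. Of the 25 genes named here as called, 18 stayed called under every alternative run. Leaving out 1 of AM_day0.1, AM_day1.2, AM_day0.2, AM_day1.1, AM_day0.3 and AM_day1.3 ended 3 to 6 of these calls, and no other single library ended more than 2. Among the lists named here, a call ended under at least 1 alternative for monocyte-derived and tissue macrophage (adjusted p = 0.52 without a filter on low counts; range 7.6e-08 to 0.52) and neutrophil markers (adjusted p = 0.078 without a filter on low counts; range 0.00046 to 0.078).

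At day 3 the interferon response persisted against day 0 and tissue macrophage genes stood higher (AM day 3, n = 3, against AM day 0, n = 3). Irf7, a transcription factor of the interferon response, rose by 4.45 ± 0.39, Oasl2 by 5.50 ± 0.47 and Cxcl9 by 5.76 ± 0.80 (largest adjusted p = 6.7e-05), with the interferon-stimulated list (17 of 24 rose, adjusted over the list alone 20, camera adjusted p = 1.2e-17, or 0.053 with an estimated correlation). Ly6c2 (6.78 ± 0.70), Hp (9.13 ± 0.49) and Itgam (7.99 ± 0.57) rose, and so did C1qb (5.91 ± 0.63), Apoe (4.62 ± 0.64) and the scavenger receptor Stab1 (6.58 ± 0.65), with a largest adjusted p of 8.2e-05. The monocyte-derived and tissue macrophage list rose (11 of 20 rose, adjusted over the list alone 14 rose and 1 fell, camera adjusted p = 4.2e-10, or 0.027 with an estimated correlation). Saa3 was at 10.98 ± 1.25, and Arg1 (arginase), a gene of tissue repair, at 8.97 ± 1.46. Tnf fell (−2.64 ± 0.43, adjusted p = 0.00031).

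Glycolysis genes stayed up (10 of 18 rose, adjusted over the list alone 15, camera adjusted p = 1.5e-21, or 0.015 with an estimated correlation), with Pfkl at 2.48 ± 0.42. Lysosome genes rose (8 of 30 rose, adjusted over the list alone 12, camera adjusted p = 3.7e-11, or 0.056 with an estimated correlation, not independent of the study's themes), among them Cd63 (2.55 ± 0.36). T and NK cell markers fell as a list (0 of 14 passed edgeR's test, 4 had an unadjusted p under 0.05 and 3 passed DESeq2's, adjusted over the list alone 0, camera adjusted p = 1.7e-08, or 0.0071 with an estimated correlation). B cell markers fell too (0 of 8 passed edgeR's test, 1 had an unadjusted p under 0.05 and 0 passed DESeq2's, adjusted over the list alone 0, camera adjusted p = 6.9e-05, or 0.048 with an estimated correlation). Neutrophil markers rose (2 of 14 rose, adjusted over the list alone 5, camera adjusted p = 0.00045, or 0.17 with an estimated correlation). The dissociation and stress response list fell (1 of 12 rose and 7 fell, adjusted over the list alone 1 and 11, camera adjusted p = 0.0010, or 0.15 with an estimated correlation), with Egr1 at −2.38 ± 0.46 and Btg2 at −1.96 ± 0.31.

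The test called 430 genes, 306 up and 124 down. The count was 993 with DESeq2, 2327 in a fit to the compared groups alone and 838 without BM_day1.3 and BM_day3.1. It was 264 without AM_day3.2, 269 without AM_day0.2 and 271 without AM_day0.1. Of the 16 genes named here as called, 16 stayed called under every alternative run.

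At day 7 a small set of genes of the monocyte and tissue macrophage lists was higher in the resident cells than at day 0 (AM day 7, n = 4, against AM day 0, n = 3). Hp (6.15 ± 0.43), Mmp14 (5.28 ± 0.44), Itgam (3.52 ± 0.46), the platelet chemokine Pf4 (4.46 ± 0.60), Cxcl9 (4.15 ± 0.72) and the lysosomal protein Cd63 (2.05 ± 0.34) were up (largest adjusted p = 0.0040). Cbln1, with 0 counts at day 0, was at least 3233-fold higher. The monocyte-derived and tissue macrophage list was up (8 of 20 rose, adjusted over the list alone 10 rose and 2 fell, camera adjusted p = 0.024, or 0.42 with an estimated correlation). Lpl rose (1.42 ± 0.30), while Siglecf (0.11 ± 0.56, adjusted p = 1.00) and Pparg (0.15 ± 0.34, adjusted p = 1.00) did not pass the test.

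Lymphocyte transcripts were lower at day 7 than at day 0. B cell markers fell (1 of 8 fell, adjusted over the list alone 7, camera adjusted p = 2.9e-12, or 0.0011 with an estimated correlation), with Ighm at −4.97 ± 1.04, and T and NK cell markers fell (0 of 14 passed edgeR's test, 7 had an unadjusted p under 0.05 and 1 passed DESeq2's, adjusted over the list alone 0, camera adjusted p = 2.3e-13, or 0.00034 with an estimated correlation). Ccl5 (−3.63 ± 0.64), Tnf (−2.33 ± 0.38) and Nfkbiz (−1.63 ± 0.28) fell, with a largest adjusted p of 0.0044, while Cxcl3 rose (2.96 ± 0.56, adjusted p = 0.0088). The Y-linked genes Eif2s3y (−7.68 ± 1.68) and Ddx3y (−7.25 ± 1.53) fell. Y-linked RNA stood at 146 to 226 CPM at day 0 and at most 4.09 CPM at day 7.

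The test called 116 genes, 70 up and 46 down. The count was 358 with DESeq2, 2578 in a fit to the compared groups alone, 219 without BM_day1.3 and BM_day3.1 and 19 with the Y-linked level as a covariate. It was 56 without AM_day0.2, 62 without AM_day0.3, 72 without AM_day0.1, 76 without AM_day7.4 and 77 without AM_day7.2. Of the 15 genes named here as called, 3 stayed called under every alternative run. 12 of them were lost with the Y-linked level as a covariate and 4 without a filter on low counts. A fit without 1 of AM_day0.2, AM_day0.3, AM_day0.1, AM_day7.3, AM_day7.1, AM_day7.2 and AM_day7.4 ended 3 to 6 of these calls, and no other single library ended more than 1. At least 1 alternative ended the call of these lists named here: monocyte-derived and tissue macrophage (adjusted p = 0.69 without a filter on low counts and 9 more alternatives; range 2.1e-05 to 0.69).

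Between day 1 and day 3 cytokine genes fell and tissue macrophage genes rose in the AM libraries (AM day 3, n = 3, against AM day 1, n = 4). Il1b (−1.62 ± 0.26), Il1a (−2.14 ± 0.39) and Cxcl3 (−2.80 ± 0.56) fell, with a largest adjusted p of 0.014, and so did the cytokine list (1 of 24 rose and 3 fell, adjusted over the list alone 1 and 13, camera adjusted p = 7.6e-12, or 0.067 with an estimated correlation), although Saa3 rose (3.51 ± 0.80). Socs3 (−1.54 ± 0.26) and Nfkb2 (−1.05 ± 0.22) fell within a falling TLR and NF-kB list (4 of 19 fell, adjusted over the list alone 8, camera adjusted p = 1.6e-08, or 0.14 with an estimated correlation). Apoe (2.66 ± 0.53) and C1qa (2.31 ± 0.45) rose (largest adjusted p = 0.014), with the monocyte-derived and tissue macrophage list (6 of 20 rose, adjusted over the list alone 11, camera adjusted p = 0.0097, or 0.43 with an estimated correlation). Ly6c2 rose by 3.22 ± 0.53 and F13a1 by 4.00 ± 0.75. Abca1 (1.72 ± 0.32) and Mfge8, a bridge between dying cells and phagocytes (2.77 ± 0.64), rose. Cell cycle genes rose (1 of 26 rose, adjusted over the list alone 8, camera adjusted p = 3.9e-06, or 0.43 with an estimated correlation), with Top2a at 2.29 ± 0.53.

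The test called 143 genes, 107 up and 36 down. The count was 905 with DESeq2, 470 without BM_day1.3 and BM_day3.1 and 268 without the BM day 1 libraries. It was 31 without AM_day3.2, 61 without AM_day1.1, 76 without AM_day3.1, 81 without AM_day1.2, 89 without AM_day3.3 and 250 without BM_day3.1. Of the 13 genes named here as called, 3 stayed called under every alternative run. 3 of them were lost with the title number as a block. Between 3 and 9 of these calls ended without 1 of AM_day3.2, AM_day1.1, AM_day3.1, AM_day1.2, AM_day1.4, AM_day3.3 and AM_day1.3, and no other single library ended more than 1. Among the lists named here, a call ended under at least 1 alternative for monocyte-derived and tissue macrophage (adjusted p = 0.19 without AM_day3.2 and 0.070 without AM_day1.4; range 6.5e-06 to 0.19).

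Between day 3 and day 7 interferon and monocyte genes fell in the AM libraries (AM day 7, n = 4, against AM day 3, n = 3). Saa3 (−9.34 ± 1.03), Nos2 (−7.44 ± 1.04) and the chemokine Ccl5 (−6.28 ± 0.71) fell, with a largest adjusted p of 0.00014, but the cytokine and chemokine list did not pass its test (3 of 24 fell, adjusted over the list alone 5, camera adjusted p = 0.31). Irf7 (−4.16 ± 0.34), Oas3 (−4.31 ± 0.39) and Rsad2 (−4.22 ± 0.63) fell (largest adjusted p = 0.00019), and so did the interferon-stimulated list (14 of 24 fell, adjusted over the list alone 21, camera adjusted p = 9.9e-21, or 0.036 with an estimated correlation). Ly6c2 (−9.25 ± 0.69), F13a1 (−6.35 ± 0.83) and Itgam (−4.47 ± 0.43) fell with the blood monocyte list (1 of 17 rose and 9 fell, adjusted over the list alone 3 and 10, camera adjusted p = 2.9e-07, or 0.021 with an estimated correlation). C1qb (−3.35 ± 0.50) and Stab1 (−4.29 ± 0.52) fell with the monocyte-derived and tissue macrophage list (8 of 20 fell, adjusted over the list alone 1 rose and 11 fell, camera adjusted p = 8.1e-10, or 0.030 with an estimated correlation). Glycolysis genes fell (10 of 18 fell, adjusted over the list alone 14, camera adjusted p = 4.8e-20, or 0.021 with an estimated correlation), with Slc2a1 at −1.38 ± 0.28. Neutrophil markers fell (2 of 14 fell, adjusted over the list alone 5, camera adjusted p = 0.0013, or 0.25 with an estimated correlation), with Lcn2 at −5.26 ± 0.72 and Csf3r at −1.48 ± 0.34. Arg1 (−5.74 ± 1.11) and the matrix protein Tgfbi (−1.57 ± 0.19) fell.

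Resident identity genes rose as a list (1 of 20 rose, adjusted over the list alone 1, camera adjusted p = 2.1e-15, or 0.030 with an estimated correlation), with Abcg1 at 1.15 ± 0.23 (adjusted p = 0.0051). In the dissociation and stress response list, Btg2 (1.19 ± 0.29) and Dusp1 (0.81 ± 0.19) rose while Ier3 fell (−1.35 ± 0.28). The Y-linked gene Eif2s3y fell (−8.10 ± 1.70). Y-linked RNA was at 194 to 227 CPM at day 3 and at most 4.09 at day 7.

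The test called 272 genes, 40 up and 232 down. The count was 179 with the library number range as a term, 677 with DESeq2, 2246 in a fit to the compared groups alone, 470 without BM_day1.3 and BM_day3.1 and 40 with the Y-linked level as a covariate. It was 135 without AM_day3.2, 167 without AM_day7.3 and 171 without AM_day7.4. Of the 21 genes named here as called, 8 stayed called under every alternative run. 12 of them were lost with the Y-linked level as a covariate and 4 with the library number range as a term. Leaving out 1 of AM_day3.2, AM_day7.3, AM_day7.2 and AM_day7.4 ended 3 to 4 of these calls, and no other single library ended more than 2. At least 1 alternative ended the call of these lists named here: alveolar macrophage identity (adjusted p = 0.19 with the Y-linked level as a covariate; range 2.7e-18 to 0.19).

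From day 1 to day 3 tissue macrophage and lysosome genes of the BM-derived cells rose and NF-kB targets fell (BM day 3, n = 4, against BM day 1, n = 5). Apoe (4.06 ± 0.49), the lipid receptor Trem2 (3.96 ± 0.78), Gpnmb (3.44 ± 0.36) and Ms4a7 (3.81 ± 0.99) rose (largest adjusted p = 0.0097), and the monocyte-derived and tissue macrophage list rose (10 of 20 rose, adjusted over the list alone 11, camera adjusted p = 3.5e-07, or 0.084 with an estimated correlation). The cathepsins Ctsd (2.44 ± 0.21) and Ctsl (2.21 ± 0.24) and the membrane protein Cd63 (2.66 ± 0.29) rose with the lysosome list (23 of 30 rose, adjusted over the list alone 25, camera adjusted p = 8.5e-17, or 0.081 with an estimated correlation, not independent of the study's themes). Oxidative phosphorylation genes rose (11 of 27 rose, adjusted over the list alone 12, camera adjusted p = 1.6e-06, or 0.15 with an estimated correlation), with Cox5b at 2.04 ± 0.29, and mitochondrial fatty acid oxidation rose (9 of 19 rose, adjusted over the list alone 9, camera adjusted p = 0.0034, or 0.081 with an estimated correlation, not independent of the study's themes), with Acadm at 1.80 ± 0.38. Arg1 (4.18 ± 0.92), the growth factor Pdgfc (4.32 ± 1.06) and the metalloprotease inhibitor Timp2 (2.33 ± 0.50) rose, while the repair and matrix list did not pass its test (9 of 20 rose and 3 fell, adjusted over the list alone 10 and 4, camera adjusted p = 0.051). Lox (7.61 ± 1.81) and Bgn (6.19 ± 1.62), genes of collagen matrix, rose, and Col1a1 (7.04 ± 2.15, adjusted p = 0.024) did so with overlapping groups. Col1a1 was the most abundant transcript of BM_day3.1 and of no other library.

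Il1b (−2.64 ± 0.24), Ptgs2 (−2.83 ± 0.51), Nfkbiz (−3.04 ± 0.27) and Rel (−2.56 ± 0.29) fell, with a largest adjusted p of 0.00039, and so did the TLR and NF-kB list (13 of 19 fell, adjusted over the list alone 14, camera adjusted p = 5.1e-09, or 0.081 with an estimated correlation). Nr4a1, a transcription factor of patrolling monocytes (−2.34 ± 0.21), Plac8 (−2.53 ± 0.53) and Ace (−2.18 ± 0.46) fell, whereas Ly6c2 (1.96 ± 0.45) and Hp (2.52 ± 0.29) rose. Among transcripts without a poly(A) tail, Rn7sk was at −12.97 ± 1.55 and Hist1h1e at −12.80 ± 1.43. Atp6v0d2 (2.30 ± 0.30), Chil3 (2.22 ± 0.35) and Lpl (1.31 ± 0.26) rose.

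The test called 4432 genes, 1818 up and 2614 down. The count was 2773 with a stricter filter on low counts, 2500 with the title number as a block and 1117 in a fit to the compared groups alone. Of the 29 genes named here as called, 24 stayed called under every alternative run. 3 of them were lost in a fit to the compared groups alone and 3 without BM_day1.3 and BM_day3.1. A fit without BM_day3.1 ended 3 of these calls.

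Between day 3 and day 7 resident genes rose and interferon genes fell in the BM libraries (BM day 7, n = 3, against BM day 3, n = 4). Siglecf (3.23 ± 0.59), Pparg (2.31 ± 0.34), Atp6v0d2 (3.26 ± 0.35) and Cidec, a lipid droplet protein (6.29 ± 1.45), rose (largest adjusted p = 0.016), and the alveolar macrophage identity list rose (13 of 20 rose, adjusted over the list alone 18, camera adjusted p = 1.0e-06, or 0.23 with an estimated correlation). The rise rests mostly on BM_day7.1 and BM_day7.2, where the mean of the list was 8.47 log2 CPM in each, while BM_day7.3 (5.92) stood close to BM_day3.2 (5.87), the highest of day 3. Ucp3, with 0 counts at day 3, was at least 650.3-fold higher. Nos2 (−5.91 ± 1.06), Ccl5 (−4.68 ± 0.73) and Saa3 (−3.71 ± 0.89) fell, as did Ifit3 (−3.47 ± 0.70), Oas3 (−3.25 ± 0.40) and Gbp2, a guanylate-binding protein (−2.93 ± 0.58), with a largest adjusted p of 0.020. The interferon-stimulated list fell (13 of 24 fell, adjusted over the list alone 18, camera adjusted p = 5.5e-17, or 0.12 with an estimated correlation). Ly6c2 (−4.52 ± 0.62) and Hp (−2.16 ± 0.35) fell with the blood monocyte list (1 of 17 rose and 6 fell, adjusted over the list alone 2 and 8, camera adjusted p = 8.4e-08, or 0.012 with an estimated correlation), and glycolysis genes fell (9 of 18 fell, adjusted over the list alone 11, camera adjusted p = 1.4e-22, or 0.012 with an estimated correlation), with Pkm at −1.61 ± 0.22.

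Cxcl1 rose by 4.58 ± 0.68, and Nfkbiz (1.62 ± 0.28), Tnfaip3 (1.19 ± 0.21) and Cd14 (0.97 ± 0.21) rose (largest adjusted p = 0.0064). Genes of the dissociation and stress response list, which sample handling can induce, rose (9 of 12 rose, adjusted over the list alone 9, camera adjusted p = 0.00048, or 0.23 with an estimated correlation), with Egr1 at 2.51 ± 0.42 and Fosb at 2.11 ± 0.39. The tetraspanin Cd9 (1.90 ± 0.21) and Plaur, the urokinase receptor (1.55 ± 0.17), rose while Tgfbi fell (−1.43 ± 0.20). Hmgcs1 rose by 1.75 ± 0.26. Apoe (0.34 ± 0.51, adjusted p = 0.83) did not pass the test.

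The test called 683 genes, 529 up and 154 down, around a median over all genes of 0.21. The count was 1686 with DESeq2, 41 in a fit to the compared groups alone, 1190 without the BM day 1 libraries and 304 with the Y-linked level as a covariate. It was 308 without BM_day7.1, 314 without BM_day7.2 and 441 without BM_day7.3. Of the 24 genes named here as called, 8 stayed called under every alternative run. 16 of them were lost in a fit to the compared groups alone. Leaving out BM_day7.1 or BM_day7.2 ended at most 2 of them.

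Changes between day 3 and day 7 were shared in part by the cell types. Of the 272 and 683 genes called, 22 rose in both (1.23 by chance), 78 fell in both (2.08 by chance) and 1 moved in opposite directions. Across all tested genes the log2 fold changes had a Pearson r of 0.172 and a Spearman rho of 0.222. Apart from leaving out 1 library, alternatives gave 5 (with the Y-linked level as a covariate) to 90 (with DESeq2) genes that rose in both. It was 3 without AM_day3.2, the lowest, and 37 without BM_day3.1, the highest. Apart from leaving out 1 library, alternatives gave 19 (with the Y-linked level as a covariate) to 160 (with DESeq2) genes that fell in both. It was 51 without AM_day3.2 and 51 without BM_day7.2.

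**Figure D3:**
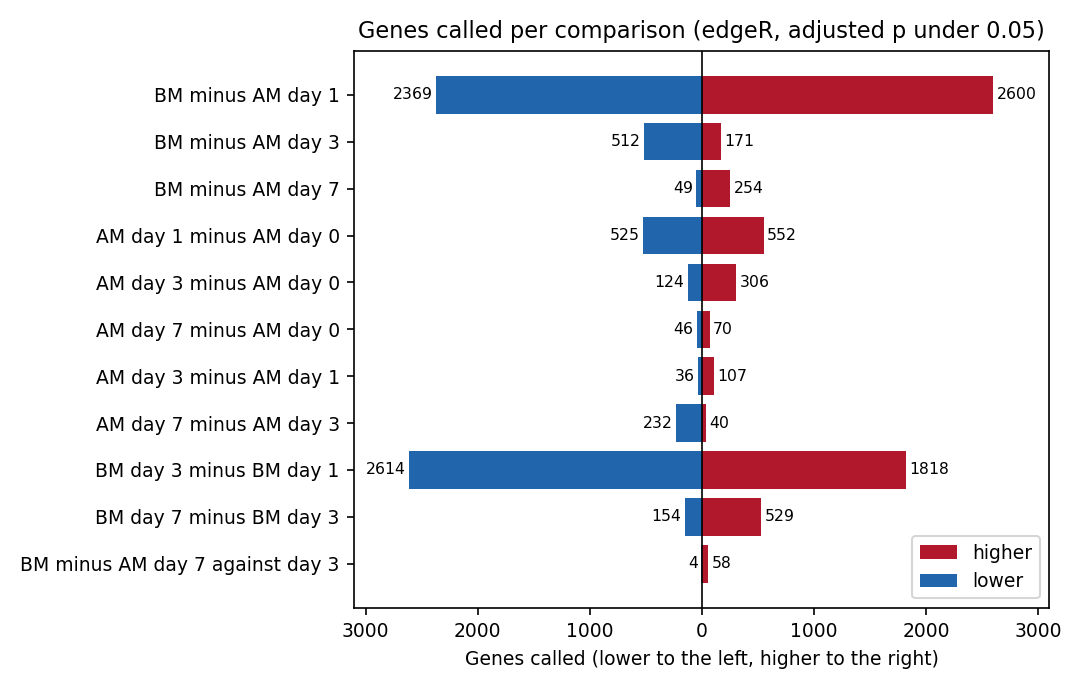
Number of genes called higher (bars to the right) and lower (bars to the left) by edgeR at an adjusted p under 0.05 in each of the 11 comparisons, on a linear axis that is 0 at the centre line. The bars are longest for BM against AM at day 1, with 4969 genes, and for BM day 3 against BM day 1, with 4432.

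Whether the distance between the cell types itself changed from day 3 to day 7 was tested with an interaction term (BM day 7, n = 3; BM day 3, n = 4; AM day 7, n = 4; AM day 3, n = 3). Some monocyte genes fell further in the resident cells than in the BM-derived cells, and the term was 4.73 ± 0.76 for Ly6c2, 3.86 ± 0.56 for Itgam and 4.71 ± 1.01 for F13a1 (largest adjusted p = 0.044). Gpnmb (3.23 ± 0.55) went the same way, as did Saa3 (5.64 ± 1.12, adjusted p = 0.031). Some genes moved toward the AM level in the BM libraries, with Atp6v0d2 at 2.95 ± 0.47 and Cd9 at 1.31 ± 0.30, as did Hmgcs1 at 1.75 ± 0.36 (largest adjusted p = 0.048). Ace, higher in BM at day 3, was at −3.42 ± 0.74. The alveolar macrophage identity list was more positive (1 of 20 more positive at day 7, adjusted over the list alone 9, camera adjusted p = 0.00028, or 0.41 with an estimated correlation), and cholesterol synthesis as well (1 of 22 more positive at day 7, adjusted over the list alone 1, camera adjusted p = 0.0032, or 0.41 with an estimated correlation). The blood monocyte list did not pass its test (3 of 17 more positive at day 7 and 1 more negative at day 7, adjusted over the list alone 6 and 1, camera adjusted p = 0.83).

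The test called 62 genes, 58 with a more positive and 4 with a more negative difference at day 7, around a median over all genes of 0.24. The count was 40 with DESeq2 size factors in edgeR, 36 without a filter on low counts, 21 with the title number as a block, 656 with DESeq2, 323 in a fit to the compared groups alone, 104 without BM_day1.3 and BM_day3.1, 168 without the BM day 1 libraries and 16 with the Y-linked level as a covariate. Leaving out 1 library moved it by over 1.5 times for 15 libraries, from 17 (AM_day7.3 or AM_day7.4) to 115 (BM_day3.2). Of the 9 genes named here as called, 3 stayed called under every alternative run. 6 of them were lost with the Y-linked level as a covariate and 5 without a filter on low counts. A fit without 1 library ended up to 5 of these calls (5 without AM_day0.2, AM_day3.2, AM_day3.3, AM_day7.2, AM_day7.3 or AM_day7.4). Among the lists named here, a call ended under at least 1 alternative for alveolar macrophage identity (adjusted p = 0.11 without a filter on low counts and 0.077 without BM_day7.2; range 4.1e-09 to 0.11) and cholesterol synthesis (adjusted p = 0.11 with the library number range as a term and 0.060 without BM_day3.2; range 3.1e-05 to 0.11).

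**Figure D4:**
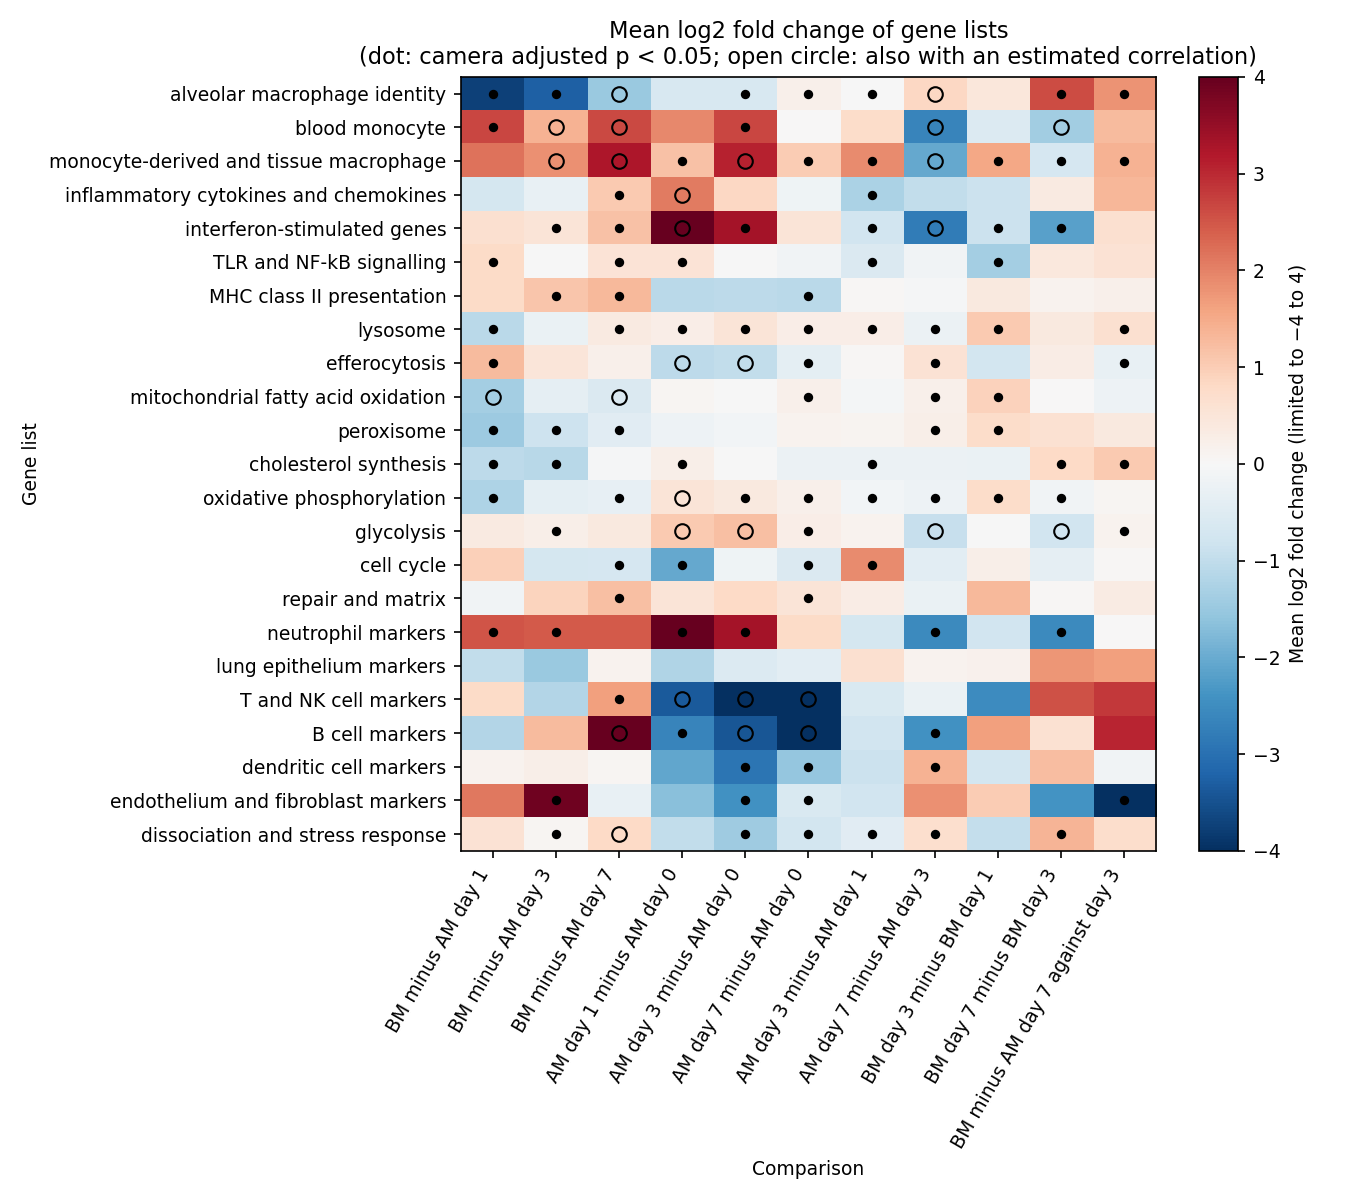
Mean log2 fold change of the tested members of the 23 tested gene lists in the 11 comparisons, as colour from blue (lower) to red (higher) on a scale held between −4 and 4. A dot marks a camera adjusted p under 0.05, and an open circle one that also holds with a correlation estimated from the data. The alveolar macrophage identity list is below 0 in BM against AM at all 3 days.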

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

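All tests of explanations in this part were chosen after the result each one concerns had been seen.

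In groups of 4 or 5 libraries each measure was searched for a library far from the rest of its group, measured by its gap to the nearest of the others as a share of the group's range. Of 116 such tests 12 found a library that stood out, where 5.8 are expected by chance, since about 1 in 20 groups gives one. BM_day1.2 had a total count of 20.01 M, and the next library of its group had 15.0. The median correlation with the group was 0.906 in AM_day1.3 (nearest other 0.934), 0.830 in BM_day1.3 (0.913) and 0.734 in BM_day3.1 (0.886). AM_day7.2 carried 4.09 CPM of Y-linked RNA, and the nearest other library 0.80. As mean log2 CPM of a list, BM_day1.3 stood low for monocyte-derived and tissue macrophage genes (3.85, nearest 5.46) and for endothelium and fibroblast markers (0.0708, nearest 1.97). AM_day1.3 stood low for interferon-stimulated genes (5.17, nearest 6.49) and AM_day7.1 high for cholesterol synthesis (5.34, nearest 4.99). BM_day3.1 stood low for MHC class II presentation (4.01, nearest 6.95), peroxisome genes (1.49, nearest 3.92) and T and NK cell markers (−2.78, nearest −1.50).

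The distance between BM and AM changed from day 3 to day 7, by the interaction term, for 62 genes. Among those named it was 4.73 for Ly6c2, 3.86 for Itgam, 4.71 for F13a1, 3.23 for Gpnmb, 5.64 for Saa3, 2.95 for Atp6v0d2, 1.31 for Cd9, 1.75 for Hmgcs1 and −3.42 for Ace (log2).

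Replication histone and small RNA transcripts, which have no poly(A) tail, were high in the BM day 1 libraries. Of 121 small RNA genes other than Rn7sk, 11 (9.09%) lay above all 21 other libraries in all 5 BM day 1 libraries, against 670 of all 17143 tested genes (3.91%, with 0.00152% by chance alone; Fisher's exact test, two-sided p = 0.0077), as a library preparation that keeps such RNA would give. More dividing cells as the whole cause are argued against by the cell cycle list, whose mean log2 CPM in BM day 1 (3.01, SD 1.85) differed by −2.06 from AM day 0 (5.07, SD 0.194), where histone levels are lower; without BM_day1.3 (0.0205) the difference was −1.32 (SD 0.933), and all 5 libraries lay below all 3 of AM day 0. Within BM day 1 the histone sum went with the list (681 CPM at 0.0205, 881 at 2.64, 1359 at 3.32, 1957 at 4.47 and 1865 at 4.58), so a share of division in it stays open. A difference of cell origin that lasts to day 3 is argued against by the day 3 histone sums, 46.0 to 106 CPM in BM. In AM they were 69.9 to 143, an overlap that the median log2 fold change per gene (−3.14, 36 of 52 below 0) hides. A library preparation may thus be the source, but all BM day 1 libraries share a name prefix that no other group has, so the preparation cannot be told apart from biology of BM-derived cells at day 1, which stays open.

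Alveolar macrophage genes were present in BM_day7.1 and BM_day7.2, but scarcely in BM_day7.3. Of 79 such genes, chosen with thresholds set after the values were seen, 9 stood under 50% of the median share in both libraries. In the single AM day 7 libraries 0, 1, 0 and 0 genes did. Those libraries served to choose the genes and hold no BM RNA, so they are no independent reference for a mixture. Whether RNA of day 7 AMs was admixed at 1 share therefore stays open. Among the 9, Epcam was at 8.71 and 9.14 CPM (AM mean 168.6 at day 7 and 15.7 at day 3). Plekha6 was at 2.94 and 3.18 CPM (AM means 194 and 4.70). Admixed RNA of the AM day 3 libraries is argued against by Y-linked RNA at 1.79% or less of its AM day 3 level. AMs in a day 3 state from mice without Y-linked RNA stay open. It stays open whether the BM-derived cells express these genes: 30 monocyte genes were at a median of 91.9% of their level in BM_day7.3, where a mixture at that share would leave 63.0%, so cells partway to the resident state may be a candidate source.

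Interferon-stimulated genes fell between day 3 and day 7 in both cell types, and the sex of the mice changed as well in part of the libraries. In BM-derived cells sex as the whole cause is argued against by the 2 day 3 libraries without Y-linked RNA, at 4.63 (BM_day3.1, which stands apart) and 5.49 (mean log2 CPM of the list). The lower lay 0.45 above the highest of the 3 day 7 libraries, which also lack it (4.07, 4.18 and 3.56). With the Y-linked level as a covariate the list fell by 1.66 (−1.66, main fit −2.17). The 2 day 3 libraries with Y-linked RNA stood higher, at 6.17 and 6.62, so a part set by sex stays open. In AMs the list fell by 2.04 (−2.04) with the Y-linked level as a covariate, but all AM day 3 libraries carry Y-linked RNA and no AM day 7 library does at that level, so sex and time cannot be told apart there. Time since LPS stays open in both.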

How the results depend on the processing

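The alternatives without BM_day1.3 and BM_day3.1, without the BM day 1 libraries and with the Y-linked level as a covariate were chosen after the data had been seen, and the others before. Of 233 gene results, 225 of them called, 128 kept their direction and their side of the threshold under every alternative run, and so did 73 of 101 list results, 69 of them called. Gene calls ended for 43 of 233 results in a fit to the compared groups alone, 46 of 233 with the Y-linked level as a covariate, not counting 3 whose direction turned and whose call ended too, 20 of 233 without a filter on low counts, 20 of 233 with the title number as a block, 19 of 114 with the library number range, 10 of 173 with the description number, 5 of 233 without BM_day1.3 and BM_day3.1, 4 of 233 with library size alone and 3 of 233 with DESeq2 size factors in edgeR. They ended for 0 with DESeq2, with a stricter filter and without the BM day 1 libraries. Leaving out 1 library at a time ended the call in 279 of 6058 gene values and 24 of 2626 list values. By the direction of the test, results turned only with the Y-linked covariate: Eif2s3y and Ddx3y in AM day 7 against day 0 went to 0.77 and 0.90, and Eif2s3y in AM day 7 against day 3 to 1.64, since the covariate is built from these genes and takes up their difference. The mean of the dendritic list in AM day 7 against day 0 went to 1.36, and the cause was not tested. For neutrophil markers the mean log2 fold change, though not the direction of camera, changed sign: to −1.35 at day 1 and −1.69 at day 3 in BM against AM with the covariate, to −0.40 in the latter without BM_day3.1 (alone or with BM_day1.3), and to 0.28 and 0.29 in BM day 7 against day 3. BM_day3.1 sets the sign in the values without it.

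The counts of called genes moved by over 1.5 times as follows. With DESeq2 size factors in edgeR it was 40 for the interaction. Without a filter on low counts it was 398 for BM against AM at day 3 and 36 for the interaction. With a stricter filter on low counts it was 2773 for BM day 3 against day 1. With the title number as a block it was 2500 for BM day 3 against day 1 and 21 for the interaction. With the library number range as a term it was 179 for AM day 7 against day 3. With DESeq2 it was 1987 for BM against AM at day 3, 615 for BM against AM at day 7, 2168 for AM day 1 against day 0, 993 for AM day 3 against day 0, 358 for AM day 7 against day 0, 905 for AM day 3 against day 1, 677 for AM day 7 against day 3, 1686 for BM day 7 against day 3 and 656 for the interaction. In a fit to the compared groups alone it was 6 for BM against AM at day 3, 2948 for BM against AM at day 7, 1862 for AM day 1 against day 0, 2327 for AM day 3 against day 0, 2578 for AM day 7 against day 0, 2246 for AM day 7 against day 3, 1117 for BM day 3 against day 1, 41 for BM day 7 against day 3 and 323 for the interaction. Without BM_day1.3 and BM_day3.1 it was 1059 for BM against AM at day 3, 612 for BM against AM at day 7, 2425 for AM day 1 against day 0, 838 for AM day 3 against day 0, 219 for AM day 7 against day 0, 470 for AM day 3 against day 1, 470 for AM day 7 against day 3 and 104 for the interaction. Without the BM day 1 libraries it was 1130 for BM against AM at day 3, 268 for AM day 3 against day 1, 1190 for BM day 7 against day 3 and 168 for the interaction. With the Y-linked level as a covariate it was 2313 for BM against AM at day 1, 188 for BM against AM at day 3, 19 for AM day 7 against day 0, 40 for AM day 7 against day 3, 304 for BM day 7 against day 3 and 16 for the interaction. The cause of these shifts was not tested.

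The overlaps between comparisons moved too (origin: BM against AM at days 3 and 7; parallel: day 7 against day 3 in AM and BM). Without a filter on low counts: r 0.0810 and rho 0.181 (origin) and r 0.129 and rho 0.172 (parallel). With a stricter filter on low counts: r 0.303 and rho 0.426 (origin) and r 0.228 and rho 0.331 (parallel). With the title number as a block: r 0.109 and rho 0.183 (origin) and higher 11, r 0.154 and rho 0.185 (parallel). With the description number as a block: r 0.195 and rho 0.306 (origin) and higher 12, r 0.247 and rho 0.295 (parallel). With the library number range as a term: lower 18 (origin) and higher 7 and rho 0.249 (parallel). With DESeq2: higher 187, lower 64, r 0.0450 and rho 0.186 (origin) and higher 90, lower 160, r 0.0273 and rho 0.173 (parallel). In a fit to the compared groups alone: higher 1, lower 2, r 0.352 and rho 0.409 (origin) and higher 8, lower 27, r 0.238 and rho 0.311 (parallel). Without BM_day1.3 and BM_day3.1: higher 144, lower 82, r 0.180 and rho 0.305 (origin) and higher 61, lower 123, r 0.203 and rho 0.246 (parallel). Without the BM day 1 libraries: lower 53, r 0.178 and rho 0.294 (origin). With the Y-linked level as a covariate: higher 33 and rho 0.244 (origin) and higher 5, lower 19, r 0.507 and rho 0.534 (parallel). Leaving out 1 library at a time gave counts from 3743 to 6395 for BM against AM at day 1, from 225 to 978 for BM against AM at day 3, from 200 to 463 for BM against AM at day 7, from 558 to 1732 for AM day 1 against day 0, from 264 to 639 for AM day 3 against day 0, from 56 to 163 for AM day 7 against day 0, from 31 to 250 for AM day 3 against day 1, from 135 to 390 for AM day 7 against day 3, from 3429 to 4628 for BM day 3 against day 1, from 308 to 876 for BM day 7 against day 3 and from 17 to 115 for the interaction. For the origin overlap this gave higher 12 to 104, lower 10 to 56, r 0.112 to 0.191 and rho 0.230 to 0.309. For the parallel overlap this gave higher 3 to 37, lower 51 to 105, r 0.133 to 0.208 and rho 0.186 to 0.249.

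The description number as a block was not run for BM day 1 and the library number range not for BM day 1 or AM day 0, since each would be confounded with the group, and DESeq2 gives no camera test. Depth limits the genes with few counts. Simulated 2-fold changes were called in 2.99% to 11.9% of genes, so a gene that is not called is not shown to be unchanged.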

Other observations

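The lists and the splits of the samples were chosen beforehand, but what the splits were to show was written down only after their results had been seen.

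Markers of cells other than macrophages were measured for contamination. The lung epithelium list did not pass camera in any of the 11 comparisons (adjusted p from 0.13 to 0.67). Of its 16 members 1 fell in AM day 1 against day 0 (adjusted over the list alone 1) and 0 passed edgeR's test in the other 10 comparisons (adjusted over the list alone 0), while 1 to 5 had an unadjusted p under 0.05 and 0 to 2 passed DESeq2's. Dendritic cell markers were lower in AM at day 3 than at day 0 (1 of 9 fell, adjusted over the list alone 1, camera adjusted p = 0.0011, or 0.077 with an estimated correlation). They were also lower at day 7 than at day 0 by camera (0 of 9 passed edgeR's test, 1 had an unadjusted p under 0.05 and 1 passed DESeq2's, adjusted over the list alone 1, camera adjusted p = 0.030, or 0.31 with an estimated correlation). This call ended without AM_day0.2 (adjusted p = 0.052), AM_day0.3 (0.078) or AM_day7.2 (0.064), and with the Y-linked level as a covariate (0.998), where the mean turned to 1.36 (range 0.0052 to 0.998). The list was higher at day 7 than at day 3 (0 of 9 passed edgeR's test, 0 had an unadjusted p under 0.05 and 0 passed DESeq2's, adjusted over the list alone 0, camera adjusted p = 0.038, or 0.25 with an estimated correlation), a call that 9 alternatives ended (range 0.0031 to 0.13). Of these, leaving out AM_day3.1 gave 0.080, AM_day3.3 0.13, AM_day7.1 0.061 and BM_day3.1 0.056. In the other 8 comparisons the dendritic list did not pass camera (adjusted p from 0.081 to 0.95), with 2 members lower in BM against AM at day 1 and 1 lower in AM day 1 against day 0. Neutrophil markers passed camera in 6 comparisons, 5 of them given in the report. The other is BM day 7 against day 3 (2 of 14 fell, adjusted over the list alone 1 rose and 8 fell, camera adjusted p = 0.00017, or 0.24 with an estimated correlation). There the mean log2 fold change went from −2.55 to 0.28 without BM_day3.1. In the remaining 5 of the 11 it did not pass (adjusted p from 0.059 to 0.55), but did under 7 alternatives in BM against AM at day 7, 3 in BM day 3 against day 1 and 1 in the interaction. The eosinophil list has 1 tested member and the erythroid list 0, so neither was tested.

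Other splits of the same libraries into groups of the same sizes were fitted, all of them or 100 drawn at random. Except for the interaction, in each comparison 1 split, the real one, reached its count. For BM against AM at day 1 the real split called more genes than all others fitted (4969, highest of the others 3193, 100 splits). So it did at day 3 (683 against 345, 35 splits) and day 7 (303 against 104, 35 splits). The same holds for AM day 1 against day 0 (1077 against 513, 35 splits), AM day 7 against day 0 (116 against 1, 35 splits), AM day 3 against day 1 (143 against 80, 35 splits) and AM day 7 against day 3 (272 against 93, 35 splits). It holds too for BM day 3 against day 1 (4432 against 1931, 100 splits) and BM day 7 against day 3 (683 against 413, 35 splits). For the interaction 2 of 100 splits, the real one included, called as many genes (62, highest of the others 89), a share under 0.05 that a draw of this size leaves uncertain. For AM day 3 against day 0, 10 splits are too few for a share under 0.05 (430 genes, highest of the others 1).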
